A study of Homo sapiens with 12 samples.

How the data were processed

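Gene expression was measured in TC71 cells, an established Ewing sarcoma line, in 3 groups at 48 h: cells with a scrambled control, with a mimic of the microRNA miR-130b, or with an inhibitor of it (anti-miR). Each group holds 4 arrays, numbered 1 to 4, so 12 arrays in all. Groups were taken from the sample labels, whose descriptions pair each sample with a column code of the raw table, and 0 columns were unmatched. The code of the anti-miR columns is not explained in the labels, so the kind of inhibitor is left open. The labels do not say whether the 4 arrays of a group come from separate cultures. P-values of single genes and of permuted arrays below therefore measure the spread between these samples. The main p-values of gene lists compare a list with other genes at a preset correlation, so they rest largely on the spread among genes.

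Per the labels' protocols, total RNA was extracted with Trizol, cleaned on columns and copied into biotin-labelled cRNA with an Illumina kit for hybridization to Illumina BeadChips. Per the file headers, the deposited raw table holds the mean signal intensity of each probe on each array, on a linear scale, for 47322 probes; its values showed no scaling between arrays. Per the file headers, it also gives a detection p-value for each probe and array. The deposited normalized table holds intensity values for the same probes that had been background-subtracted and brought to a common distribution on all 12 arrays; the method is not stated, the median was 12 on every array, and 159270 values lay below 0. Median raw intensity per array was 85.5 to 88.8 in the scramble group, 84.5 to 87.6 in the mimic group and 72 to 82.5 in the anti-miR group. The number of arrays limits the precision of every comparison.

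The raw intensities were corrected for background with limma's normexp model, with the background estimated from the detection p-values and an offset of 16, then quantile normalized and converted to log2 (limma 3.58.1, R 4.3.3). A probe was kept when its detection p was under 0.05 on at least 4 of the 12 arrays, which left 20768 probes. The platform's gene table named 1 gene for 30113 of all probes and several genes for 8, and gave no name used here for 17201; Entrez identifiers matched the reference gene table for 30074 probes and not for 39. Of the probes kept, 15758 had a gene name. Each gene was represented by its brightest probe, which gave 11835 genes, 3112 of them with several probes. Probes without a name were tested apart and enter no count of genes.

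A linear model with 1 mean per group was fitted to all 12 arrays with limma, and 3 contrasts were taken: mimic minus scramble, anti-miR minus scramble, and mimic minus anti-miR. P-values came from limma's moderated statistic with a Benjamini-Hochberg adjustment within each contrast, and a gene was called changed at an adjusted p under 0.05. The procedure was tested on simulated data for mimic against scramble on 11835 genes: it recovered 70% of 100 genes changed by 0.5 on the log2 scale and 100% of 100 genes changed by 1, with 4 false calls among 181; a further 7 calls fell on the 25 genes that had been shifted by 0.3 to test the list test.

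A set of 28 gene lists was fixed before the data were examined: literature targets of the miR-130 family, CDC42 and PAK signalling, AP-1 subunits, AP-1 associated and immediate early genes, JNK and MAP kinase components, genes activated and genes repressed by EWS-FLI1, mesenchymal and matrix genes, TGF-beta and BMP signalling, G1/S and DNA replication, G2/M and mitosis, p53 targets and cell cycle inhibitors, sterol biosynthesis, interferon-stimulated genes, NF-kappaB and inflammatory genes, the unfolded protein and amino acid stress response, hypoxia and glycolysis, RNA interference machinery, autophagy and lysosome, neuronal differentiation, cytosolic ribosomal proteins, the mitochondrial respiratory chain, heat shock and chaperones, and markers of fibroblasts, epithelium, blood cells and endothelium. The lists were compiled from general knowledge, not from a database. They hold 717 symbols, of which 664 were on the array and 539 were tested. Over all listed genes 18 older symbols were replaced by current ones. Each list was tested in each contrast with limma's camera at a preset correlation between genes of 0.01, with a Benjamini-Hochberg adjustment over the 84 tests; camera compares the list with all other genes tested. Camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance, were run as alternatives. A further 5 lists were written after the largest changes had been seen, the last of them after the other 4 had been tested, and appear only at the end.

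Genes named in the text follow a rule fixed before the data were examined. It takes ARHGAP1, CDC42, the AP-1 subunits FOS, FOSB, FOSL1, FOSL2, JUN, JUNB, JUND and ATF3, and the microRNA's own gene. It takes the 10 largest rises and the 10 largest falls per comparison with scramble among called genes whose groups of arrays do not overlap and whose probe was detected on all 4 arrays of a group. It takes up to 4 called members of each list with the largest changes, and up to 10 genes called in opposite directions in both comparisons. TXNIP, members named for the direct contrast of mimic and anti-miR, the genes called in the same direction in both comparisons and members of the 5 later lists fall outside the rule and were chosen after their values were seen. Of the 28 lists 1, and some genes that the rule or the lists take, are not reported here.

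For comparisons of array means of a list, exact two-sided permutation tests over the 70 assignments of 8 arrays were used, whose smallest possible p is 0.0286. Overlaps between comparisons that share the scramble arrays are given beside 100 simulations and beside 6 splits of the measured scramble arrays. In the simulations all groups, scramble included, were unchanged and each gene was drawn on its own. Alternatives covered the background correction, the normalization, the filter, the choice of probe, the replicate number as a block, the arrays in the fit, array weights, the variance model, stricter thresholds and leaving out each array in turn; leaving out both arrays of lowest raw intensity and adding the raw intensity as a covariate were chosen after seeing the data. Tests of miR-130b seed sites in 3' untranslated regions had been planned and were not run, because transcript sequences were not used here. An array slide as a block was not run, because the tables give no slide.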

Results

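The series measured gene expression on BeadChip arrays in TC71 Ewing sarcoma cells at 48 h, in 3 groups of 4 arrays: cells with a scrambled control, with a miR-130b mimic or with a miR-130b inhibitor (anti-miR). Between 19008 and 20544 of the 47322 probes were detected per array. The mimic arrays separated from the other 8 on the first principal component, which carried 32.9% of the variance, and correlations between arrays of a group were 0.990 to 0.994. Median raw intensity was lower on the anti-miR arrays (72 to 82.5) than on the scramble arrays (85.5 to 88.8) and the mimic arrays (84.5 to 87.6). Changes of genes are log2 fold changes ± limma's moderated standard error with 4 arrays per group, and adjusted p-values are limma's over the 11835 genes tested. This error pools the spread within all 3 groups and is drawn towards that of other genes. It can therefore understate the spread of a gene that varies more in the groups compared than in the remaining group. For lists, adjusted p-values are from camera over 84 tests.

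The comparison of mimic with scramble asks what raised miR-130b does to its proposed target ARHGAP1 and to signalling through CDC42 and AP-1. ARHGAP1, a GTPase activating protein that switches CDC42 off, fell by 0.58 ± 0.14 (adjusted p = 0.015) under the mimic, from 8.74 ± 0.02 to 8.16 ± 0.38 log2 units (SD, n = 4). Every mimic array (7.68 to 8.48) lay below every scramble array (8.71 to 8.76). Of 27 measured literature targets of the miR-130 family, out of 41 listed, 8 fell, 1 rose and 18 did not pass (1 higher and 9 lower when adjusted over the list alone). IRF1, a transcription factor of the interferon response, changed by -0.80 ± 0.18, adjusted p = 0.0107. RAB5A, an early endosome GTPase, changed by -0.63 ± 0.10, adjusted p = 0.00232, and the BMP receptor gene ACVR1 changed by -0.63 ± 0.10, adjusted p = 0.00232. RUNX3, a Runt-family transcription factor, changed by -0.63 ± 0.09, adjusted p = 0.00156, although its second probe, detected on 4 arrays, read 0.09. The list was lower (mean -0.17, adjusted p = 0.0307), with an adjusted p = 0.479 with an estimated correlation. Without scramble array 1 the list's adjusted p was 0.0515 (mean -0.15).

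CDC42 transcript itself gave -0.21 ± 0.14, adjusted p = 0.319, and its 3 detected probes read -0.21, 0.43 and -0.11, none past the threshold. In the CDC42 and PAK signalling list 33 of 40 genes were measured, and 1 rose, 3 fell and 29 did not pass (the same 1 and 3 adjusted over the list alone). WASL, the N-WASP activator of actin branching that CDC42 engages, changed by -0.57 ± 0.09, adjusted p = 0.00234, and its partner gene WIPF1 by -0.51 ± 0.13, adjusted p = 0.0182, while ARHGDIA rose by 0.35 ± 0.09 (adjusted p = 0.0197). The list was not called (mean -0.05, adjusted p = 0.725). Single arrays decided some of these genes: WIPF1 was no longer called without scramble 1, 2 or 3 (adjusted p up to 0.0547) and ARHGDIA without scramble 1 or mimic 4 (0.0602 and 0.0591). A second probe of WIPF1 read -0.10.

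Several AP-1 genes rose with the mimic. JUN, the best-known partner in AP-1 dimers, rose by 0.88 ± 0.13 (adjusted p = 0.00152), from 8.40 ± 0.29 to 9.28 ± 0.12 log2 units (SD, n = 4), a 1.84-fold change. ATF3, a stress-induced member of the family, rose by 0.68 ± 0.19 (adjusted p = 0.0285). The small Maf genes moved apart, MAFG by 0.57 ± 0.13, adjusted p = 0.00954 and MAFF by -0.50 ± 0.14, adjusted p = 0.0238. Of 13 measured AP-1 subunit genes, out of 20 listed, 3 rose, 1 fell and 9 did not pass (6 higher and 1 lower adjusted over the list alone). Those that did not pass include FOSL1 (0.26), FOSL2 (0.21), JUNB (0.22) and JUND (0.19). The FOS probe was detected on 0 arrays and the FOSB probe on 3 of 12, so neither was tested. The probe for the microRNA's own gene, which reads precursor RNA and checks neither reagent, was detected on 0 arrays. The subunit list was higher (mean 0.32, adjusted p = 0.00287), with an adjusted p = 0.379 with an estimated correlation. The ATF3 call was lost without scramble 2, 3 or 4 (adjusted p 0.0796, 0.08 and 0.063) and without mimic 2 or 3 (0.0633 and 0.0785), under median scaling of the arrays (0.0659) and with no filter on dim probes (0.0505). The MAFF call was lost without scramble 1 or 2 (0.0724 and 0.0666) and mimic 3 or 4 (0.053 and 0.0648).

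Some genes that AP-1 and growth factor signals are known to induce rose as well. CXCL8, which encodes the chemokine interleukin 8, rose by 1.51 ± 0.21 (adjusted p = 0.00127), from 5.77 ± 0.19 to 7.28 ± 0.47 log2 units (SD, n = 4), and its second probe read 0.78. The MAP kinase phosphatase genes DUSP5 (0.76 ± 0.12, adjusted p = 0.00183) and DUSP2 (0.71 ± 0.10, adjusted p = 0.00127) and the haem oxygenase gene HMOX1 (0.76 ± 0.17, adjusted p = 0.00969) rose. Of 30 measured AP-1 associated and immediate early genes 8 rose and 22 did not pass (10 higher and 1 lower adjusted over the list alone), and the list was higher (mean 0.21, adjusted p = 0.00479; adjusted p = 0.379 with an estimated correlation). In the JNK and MAP kinase list 16 genes were measured, 4 rose, 1 fell and 11 did not pass (6 higher and 1 lower adjusted over the list alone). They include MAP2K4, the kinase that activates JNK (0.60 ± 0.09, adjusted p = 0.00191), MAPKAPK2 (0.47 ± 0.09, adjusted p = 0.00526) and the JNK1 gene MAPK8 (0.44 ± 0.12, adjusted p = 0.0259). The JNK list missed the threshold (mean 0.16, adjusted p = 0.0583). MAPK8 was not called without scramble 3 (adjusted p = 0.079), mimic 1 (0.0609) or mimic 4 (0.059), nor under median scaling (0.0878).

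**Figure D1:**
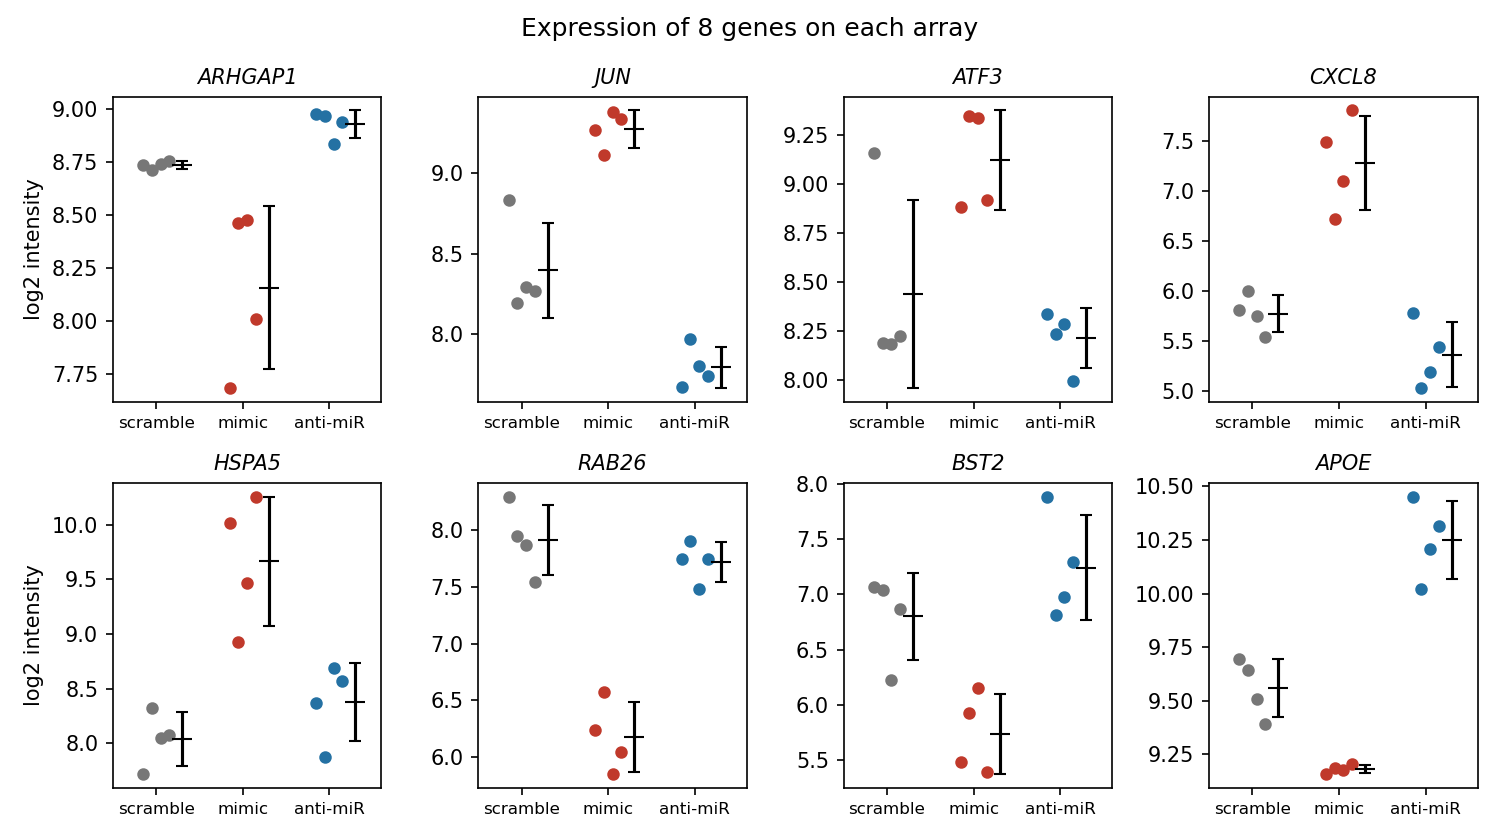
Log2 intensity of 8 genes on each array of the scramble, mimic and anti-miR groups; points are arrays and bars the group mean with its standard deviation (n = 4). ARHGAP1 lies between 7.68 and 8.48 on the mimic arrays, below all scramble arrays, and JUN, CXCL8 and HSPA5 are highest under the mimic.

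Over all genes the mimic changed 1919 of 11835 (16.2%), 881 higher and 1038 lower. Median scaling in place of quantile normalization called 1444, 500 higher and 944 lower, so that 34.6% of calls were rises against 45.9%. An unadjusted p under 0.05 was reached by 3829 genes where 592 would be by chance. Most changes were small: the median size among changed genes was 0.45, 11 genes rose and 20 fell by at least 2-fold. Among called genes whose groups of arrays do not overlap and whose probe was detected on all 4 arrays of a group, the largest rises were HSPA5, the endoplasmic reticulum chaperone BiP (1.63 ± 0.25, adjusted p = 0.00174), CXCL8, ZCCHC12 (1.29 ± 0.13, adjusted p = 0.000407) and the serum and glucocorticoid induced kinase gene SGK1 (1.25 ± 0.13, adjusted p = 0.000477), whose 3 probes lay close together. CD36, NQO1, ARID3B, TIMP3, SRPRA and SNORA63 rose by 0.99 to 1.07. By the same limits the largest falls were RAB26, a GTPase of secretory vesicles (-1.73 ± 0.16, adjusted p = 0.000407), SBF2 (-1.37 ± 0.16, adjusted p = 0.00108; second probe -0.43, not called), DEPTOR, an inhibitor of mTOR kinase (-1.24 ± 0.21, adjusted p = 0.0029), and OPLAH, an enzyme of glutathione turnover (-1.20 ± 0.14, adjusted p = 0.000965). ABTB1 was detected on 0 of 4 mimic arrays and was at least 1.85-fold lower. CCNG2, KLHL24, LAMB2P1, BST2 and CLYBL changed by -1.06 to -1.10. Leaving out 1 array moved the count of changed genes by over 1.5 times for scramble 1 (1089), mimic 3 (1210) and mimic 4 (1176).

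Protein folding genes were higher as groups under the mimic. HSPA5 went from 8.04 ± 0.25 to 9.67 ± 0.59 log2 units (SD, n = 4), 3.09-fold, and the chaperone cofactor genes SDF2L1 (0.72 ± 0.17, adjusted p = 0.0134) and CRELD2 (0.68 ± 0.14, adjusted p = 0.00775) rose with it. Of 27 measured genes of the unfolded protein and amino acid stress response 7 rose, 0 fell and 20 did not pass (10 higher adjusted over the list alone), and the list mean was 0.42 (adjusted p = 1.36e-05; adjusted p = 0.379 with an estimated correlation). Among 17 measured heat shock and chaperone genes 8 rose and 9 did not pass (10 higher adjusted over the list alone). They include the HSP40 genes DNAJA1 (0.77 ± 0.14, adjusted p = 0.00399) and DNAJB1 (0.53 ± 0.13, adjusted p = 0.0148), the HSP110 gene HSPH1 (0.68 ± 0.12, adjusted p = 0.00306) and CHORDC1 (0.61 ± 0.10, adjusted p = 0.00263). The heat shock list mean was 0.34 (adjusted p = 3.58e-05; adjusted p = 0.613 with an estimated correlation).

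Genes of DNA replication and of sterol synthesis were higher as groups. CDC25A, the phosphatase that opens S phase, rose by 0.99 ± 0.18 (adjusted p = 0.00421), and CCNE1, which encodes cyclin E1, by 0.76 ± 0.16 (adjusted p = 0.00699); RRM2 (0.61 ± 0.17, adjusted p = 0.0275) and FEN1 (0.54 ± 0.16, adjusted p = 0.036) also rose. Of 27 measured G1/S and DNA replication genes 10 rose and 17 did not pass (13 higher adjusted over the list alone; mean 0.30, adjusted p = 1.55e-05; adjusted p = 0.613 with an estimated correlation). The fry test did not call this list (adjusted p = 0.0544). Of 30 G2/M and mitosis genes only CCNB1, which encodes cyclin B1, changed (-0.42 ± 0.11, adjusted p = 0.0182), and that list was not called (1 lower adjusted over the list alone; mean -0.02, adjusted p = 0.851). In the sterol list 27 genes were measured, 8 rose and 19 did not pass (12 higher adjusted over the list alone), among them DHCR7 (0.82 ± 0.15, adjusted p = 0.00419), ACAT2 (0.74 ± 0.12, adjusted p = 0.00262), HMGCS1 (0.68 ± 0.19, adjusted p = 0.0252) and MVD (0.54 ± 0.13, adjusted p = 0.0119), all enzymes of cholesterol synthesis. Its mean was 0.21 (adjusted p = 0.00615; adjusted p = 0.613 with an estimated correlation). Camera also called both lists higher under the anti-miR against the same scramble arrays (means of 0.14 for G1/S and 0.08 for sterol). Between the reagents the sterol list was not called (mean 0.13, camera adjusted p = 0.265), and the G1/S list was (mean 0.16, adjusted p = 0.0420). Calls near the threshold rested on single arrays: RRM2 was lost without scramble 1, 2 or 3 and mimic 3 or 4 (adjusted p up to 0.0804), FEN1 without scramble 1 or 3 or any mimic array (up to 0.107) and in 1 of 10 other settings (0.0606), HMGCS1 without scramble 1 or mimic 1 or 4 (up to 0.0761) and CCNB1 without mimic 1 or 4 (up to 0.0582).

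Interferon-stimulated genes were lower. BST2, which encodes the antiviral membrane protein tetherin, fell by 1.07 ± 0.24 (adjusted p = 0.0103), from 6.80 ± 0.39 to 5.73 ± 0.36 log2 units (SD, n = 4). IRF1 (-0.80), IFITM1 (-0.57 ± 0.12, adjusted p = 0.00736) and IFIT2 (-0.68 ± 0.20, adjusted p = 0.0361) fell with it. Of 30 measured members, out of 40 listed, 9 fell, 0 rose and 21 did not pass (13 lower adjusted over the list alone). The list mean was -0.31 (adjusted p = 0.000257; adjusted p = 0.613 with an estimated correlation). The IFIT2 call was lost without any 1 of the 4 scramble arrays and without mimic 1 or 4 (adjusted p up to 0.0988), and in 2 of 10 other settings (up to 0.0638). CXCL8 was the only called gene of 10 measured NF-kappaB and inflammatory genes (also adjusted over the list alone; list mean 0.20, adjusted p = 0.266).

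**Figure D2:**
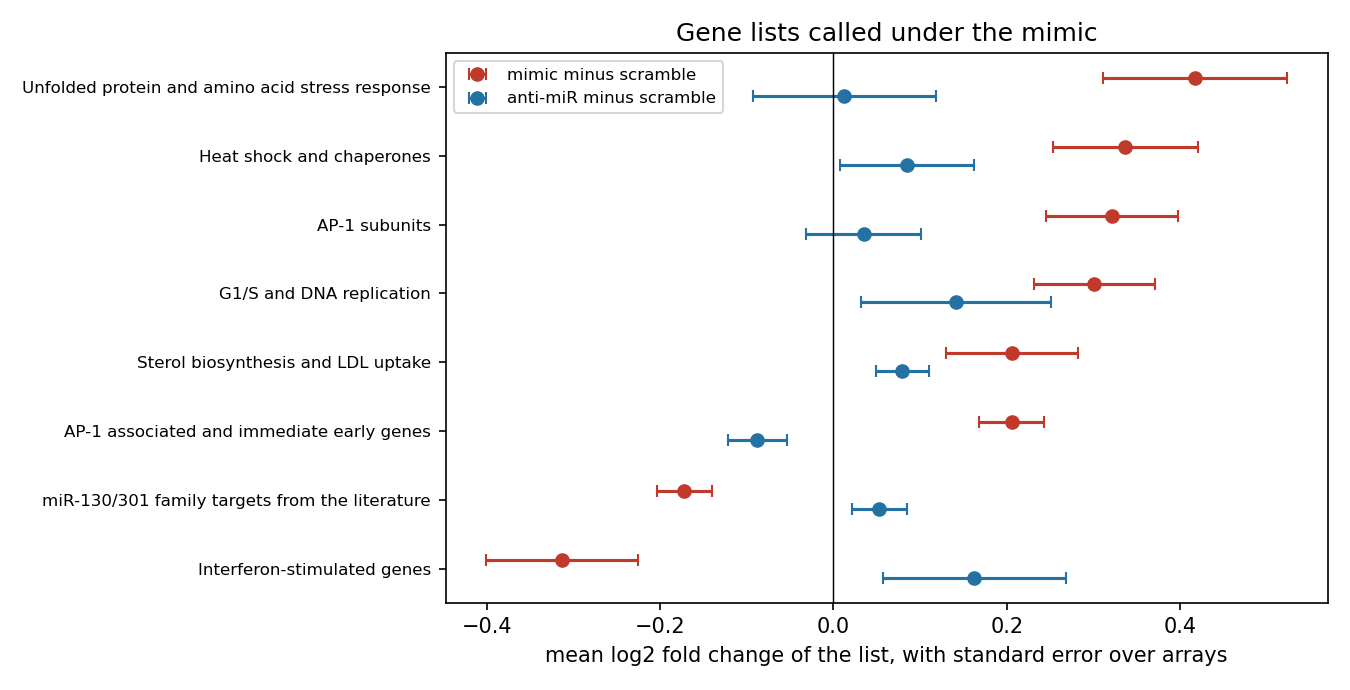
Mean log2 fold change, with its standard error over arrays, of the 8 gene lists called under the mimic, for mimic minus scramble and anti-miR minus scramble. The unfolded protein list stands at 0.42 and the interferon list at -0.31 under the mimic.

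The remaining lists were not called under the mimic. In hypoxia and glycolysis 4 of 26 measured genes rose and 22 did not pass (6 higher adjusted over the list alone; mean 0.17, adjusted p = 0.0534), namely the glucose transporter gene SLC2A3 (0.80), VEGFA (0.54), PGAM1 (0.50) and PFKFB3 (0.48). Of 34 genes that the Ewing sarcoma fusion EWS-FLI1 activates 4 rose and 5 fell (5 and 6 adjusted over the list alone; mean 0.01, adjusted p = 0.725), with HOXD13 at 0.45, CAV1 at 0.43 and FCGRT at -0.44. Of 21 genes it represses 4 rose and 1 fell (the same adjusted over the list alone; mean 0.11, adjusted p = 0.385), among them the matrix genes TIMP3 (1.00) and COL1A1 (0.76). Of 22 mesenchymal and matrix genes 2 rose and 3 fell (the same adjusted over the list alone; mean -0.04, adjusted p = 0.725), with LAMB1 at -0.41. The brightest TNC probe read -0.40 (called) and its second probe 0.60. When limma was fitted to every probe kept, the second probe passed (adjusted p = 0.0253) and the brightest did not (0.0586). TNC is counted as a fall here and among the genes that EWS-FLI1 represses, but its direction stays open. Of 23 TGF-beta and BMP genes 3 rose and 3 fell (4 and 4 adjusted over the list alone; adjusted p = 0.862), with ACVR1 at -0.63, BMP2 at 0.61 and ID1 at -0.45. Of 22 p53 targets and cell cycle inhibitors 1 rose, AEN (0.72), and 2 fell, CCNG2 (-1.10) and ZMAT3 (-0.44, other probes -1.16); its mean was -0.03 (2 and 2 adjusted over the list alone; adjusted p = 0.725). Of 20 RNA interference genes 3 rose and 4 fell (3 and 6 adjusted over the list alone; mean -0.06, adjusted p = 0.414), with LIN28B, which blocks let-7 maturation, at 0.67 ± 0.14, adjusted p = 0.00725 and the deadenylase gene PAN2 at -0.53; CNOT1 read -0.43 and its second probe 0.06, and with the mean of its probes it was not called (-0.19, adjusted p = 0.269).

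Of 24 autophagy and lysosome genes 1 rose, SQSTM1 (0.47), and 3 fell, CTSA (-0.54), UVRAG (-0.39, second probe -0.10, and an adjusted p = 0.105 with the mean of its probes) and LAMP2 (-0.33, with 5 other probes at -0.09 to 0.19), under a list mean of 0.02 (adjusted p = 0.818). Of 13 neuronal differentiation genes 4 rose and 1 fell (mean 0.09, adjusted p = 0.668), with the growth cone gene GAP43 at 0.67 ± 0.10, adjusted p = 0.00152, the neurofilament gene NEFH at 0.55 and NEUROG2 at -0.58. RPL7 (-0.48) was the only called gene of 22 cytosolic ribosomal proteins (mean -0.07, adjusted p = 0.442), and 0 of 23 respiratory chain genes changed (mean -0.03, adjusted p = 0.725). Counts in these 4 lists were the same adjusted over the list alone. Marker lists of other cell types were not called: fibroblast (9 measured; COL1A1 and THY1 rose, THY1 by 0.62 ± 0.12 (adjusted p = 0.00427), and FAP fell; 2 higher and 3 lower adjusted over the list alone; adjusted p = 0.818), epithelial (3 measured; KRT8 0.87; mean 0.18 but median -0.14; adjusted p = 0.798), blood cell (6 measured, 0 changed, adjusted p = 0.851) and endothelial (2 measured, 0 changed, 1 lower adjusted over the list alone, adjusted p = 0.439).

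Several of the members named in these lists lay near the threshold and were called or not according to single arrays. BMP2 was lost without scramble 1 or 3 or mimic 4 (adjusted p 0.068, 0.062 and 0.0529), PFKFB3 without scramble 1 or mimic 1 or 4 (0.0656, 0.0595 and 0.0611), and LAMP2 without scramble 2 or mimic 3 or 4 (0.0606, 0.0548 and 0.0509). SLC2A3 was lost without scramble 1, 2 or 4 or mimic 1 or 4 (up to 0.113), and TNC in all but 2 of the 12 leave-outs, those of scramble 3 and mimic 1 (up to 0.138). FAP was lost in all but 3, those of mimic 3 and anti-miR 2 and 3 (up to 0.14). The connective tissue growth factor gene CCN2 (0.45 ± 0.14, adjusted p = 0.0462) was lost in all but 3, those of mimic 3 and anti-miR 1 and 2 (up to 0.133), and in 8 of 9 other settings (value down to 0.21, adjusted p up to 0.214); its second probe read 0.07. Of 10 other settings TNC was lost in 4 and reversed in 1, FAP lost in 4, MAP3K7 in 5, NEFM in 4, KCNAB3 and SLC2A3 in 3 each and ACVR2B in 2, and LAMP2 reversed in 1. KCNAB3, an EWS-FLI1 activated gene (-0.49 ± 0.15, adjusted p = 0.042), was lost without scramble 2, 3 or 4 or mimic 1, 3 or 4 (up to 0.113). MAP3K7 (0.29 ± 0.09, adjusted p = 0.0491) was lost without any scramble array, mimic 1 or 4, or anti-miR 1 or 3 (up to 0.128), NEFM (0.46 ± 0.14, adjusted p = 0.0354) without scramble 1, 2 or 4 or mimic 1, 3 or 4 (up to 0.105), TWIST1 (0.42 ± 0.11, adjusted p = 0.0173) without scramble 1 or mimic 1 (0.055 and 0.0506), and ACVR2B (0.40 ± 0.11, adjusted p = 0.0275) without scramble 1 or 4 or mimic 4 (up to 0.0828).

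The comparison of anti-miR with scramble asks what lowering the cell's own miR-130b does. It called 15 genes, 8 higher and 7 lower, none of them ARHGAP1 (0.19 ± 0.14, adjusted p = 0.509), CDC42 (0.04), JUN (-0.60 ± 0.13, adjusted p = 0.0853) or ATF3 (-0.22). PTPMT1, a mitochondrial phosphatase of cardiolipin synthesis, rose by 0.76 ± 0.12 (adjusted p = 0.0441), APOE, which encodes the lipid carrier apolipoprotein E, by 0.69 ± 0.10 (adjusted p = 0.0441), and ADI1, an enzyme of methionine salvage, by 0.60 ± 0.10 (adjusted p = 0.0441). SYBU, which encodes a kinesin adaptor of axonal transport, rose by 0.60 ± 0.09 (adjusted p = 0.0441) and the carbonic anhydrase relative CA11 by 0.48 ± 0.08 (adjusted p = 0.0478). ZNF804A and SPOCK2, each detected on 0 of 4 scramble arrays, were at least 1.36-fold and 1.37-fold higher. Among the falls, GALNT16 changed by -0.75 ± 0.13, adjusted p = 0.0478, the carbonic anhydrase gene CA5B by -0.71 ± 0.12, adjusted p = 0.0478, the growth factor gene BMP6 by -0.69 ± 0.11, adjusted p = 0.0441, the ciliary gene BBS2 by -0.55 ± 0.09, adjusted p = 0.0441 and GRIK2, a glutamate receptor gene, by -0.43 ± 0.07, adjusted p = 0.0478 (other probes -0.16 and -0.04). ADAM32 and DLX4, each detected on 0 of 4 anti-miR arrays, were at least 1.32-fold and 1.09-fold lower. JUN, not called here, passed with no background correction (adjusted p = 0.0348) or a normexp offset of 50 (0.0414).

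Of the 28 lists 3 were called under the anti-miR, each without a single called member: G1/S and DNA replication (27 measured, mean 0.14, adjusted p = 0.00161), interferon-stimulated genes (30 measured, mean 0.16, adjusted p = 0.00533) and sterol biosynthesis (27 measured, mean 0.08, adjusted p = 0.0391). These gave adjusted p = 0.752, adjusted p = 0.702 and adjusted p = 0.724 with an estimated correlation, and fry called none of the 3. Adjusted over the list alone, 0, 2 and 0 members were higher. The literature targets of the miR-130 family had a mean of 0.05 (adjusted p = 0.290) and the AP-1 associated genes of -0.09 (adjusted p = 0.256). In 4 further lists, none of them called, mean and median differed in sign: EWS-FLI1 activated genes, blood cell markers, hypoxia and glycolysis, and autophagy and lysosome.

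The anti-miR calls rest on single arrays and on settings, and the anti-miR arrays also had the lower raw intensity. The count was 0 without scramble 1, 2 or 3, without mimic 1 or 4 or without anti-miR 1, 3 or 4, 1 without scramble 4, 10 without mimic 2, and 31 without anti-miR 2. It was 0 under median scaling, with only the groups compared in the fit, without both arrays of lowest intensity, or with raw intensity as a covariate. In the main fit 1958 genes reached an unadjusted p under 0.05 where 592 would by chance. The G1/S list was lost without scramble 1 (mean 0.09, adjusted p = 0.0643) and without both arrays of lowest intensity (adjusted p = 0.862), and with the raw intensity covariate its mean was -0.12. The interferon list was lost without anti-miR 1 (mean 0.09, adjusted p = 0.146) and with no filter on dim probes (0.0638), and the sterol list without scramble 1 or 4 or anti-miR 2 or 3 (adjusted p 0.102, 0.105, 0.0689 and 0.0614). The sterol list was also lost with genes detected on all 12 arrays (0.0609), without both arrays of lowest intensity (0.0774) and with the raw intensity covariate (mean 0.02, adjusted p = 0.646). Each called gene named for the anti-miR above was no longer called in 4 to 8 of its 9 or 10 other settings.

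The direct contrast of mimic and anti-miR sets the 2 reagents, meant to raise and to lower miR-130b, against each other and uses no scramble arrays as a control. JUN was higher with the mimic by 1.48 ± 0.13 (adjusted p = 0.000125), 2.79-fold, CXCL8 by 1.92 ± 0.21 (adjusted p = 0.000194), and ATF3 by 0.91 ± 0.19 (adjusted p = 0.00824). ARHGAP1 was lower by 0.77 ± 0.14 (adjusted p = 0.00384) and each of the 4 mimic arrays (7.68 to 8.48) lay below each anti-miR array (8.84 to 8.98). Of 11835 genes 1777 differed, 926 higher and 851 lower with the mimic, and 3683 reached an unadjusted p under 0.05. The count fell to 877 without mimic 1 and 957 without mimic 4, to 1021 without both arrays of lowest intensity and to 828 with raw intensity as a covariate.

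Of the lists, 10 were called in this contrast. Interferon-stimulated genes were lower with the mimic (mean -0.48, adjusted p = 2.05e-08; adjusted p = 0.379 with an estimated correlation), with 13 of 30 members lower and 0 higher (17 lower adjusted over the list alone), among them BST2 (-1.51), IRF1 (-1.18), OASL (-0.98) and IFITM1 (-0.78). Literature targets of the miR-130 family were lower (mean -0.22, adjusted p = 0.00175; adjusted p = 0.379 with an estimated correlation), 7 of 27 lower and 0 higher by either adjustment. AP-1 associated genes were higher (mean 0.29, adjusted p = 0.000193; adjusted p = 0.379 with an estimated correlation), 14 of 30 higher and 1 lower (15 and 1 adjusted over the list alone); KLF2 read 1.21 and the exception, EGR1, -1.28. The unfolded protein response was higher (mean 0.40, adjusted p = 2.92e-05; adjusted p = 0.410 with an estimated correlation), 8 of 27 higher (12 adjusted over the list alone), and so were heat shock genes (mean 0.25, adjusted p = 0.00175; adjusted p = 0.639 with an estimated correlation), 4 of 17 higher (5 adjusted over the list alone).

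The other 5 lists called were all higher with the mimic. NF-kappaB and inflammatory genes had a mean of 0.36 (adjusted p = 0.0200; adjusted p = 0.379 with an estimated correlation) with CXCL8 and PTGS2 (0.63) higher of 10. JNK and MAP kinase components had 0.20 (adjusted p = 0.0307; adjusted p = 0.613 with an estimated correlation), 5 higher and 1 lower of 16 (7 and 1 adjusted over the list alone). EWS-FLI1 repressed genes had 0.21 (adjusted p = 0.0391; adjusted p = 0.613 with an estimated correlation), 7 of 21 higher, among them COL1A1 (0.81) and CCN1 (0.73). G1/S genes had 0.16 (adjusted p = 0.0420; adjusted p = 0.845 with an estimated correlation), 3 of 27 higher. AP-1 subunits had 0.29 (adjusted p = 0.0489; adjusted p = 0.582 with an estimated correlation), 4 of 13 higher: JUN, ATF3, MAFG (0.49) and JUND (0.35). Where no other count is given, the counts of these 5 lists were the same adjusted over the list alone. Several of these calls ended when 1 array was left out: JNK without mimic 4 or anti-miR 3 (adjusted p 0.0634 and 0.0557), EWS-FLI1 repressed genes without mimic 1 or 4 or anti-miR 3 or 4 (up to 0.11), G1/S without mimic 2 or 3 or anti-miR 1 or 2 (up to 0.532), and AP-1 subunits without any anti-miR array, scramble 2 or 4 or mimic 3 or 4 (up to 0.102). Among 13 other settings, the estimated correlation included, AP-1 subunits were lost in 9 (mean 0.21 to 0.39, adjusted p up to 0.582) and EWS-FLI1 repressed genes in 4, those with genes detected on all 12 arrays (0.0811), without both arrays of lowest intensity (0.136) and with raw intensity as a covariate (0.137) besides. NF-kappaB genes were lost in 2 (mean 0.15, adjusted p = 0.230 with genes detected on all 12 arrays), JNK in 2 (0.0532 with the mean of the probes) and G1/S in 2 (0.339 by fry). Of the 18 lists not called, mean and median differed in sign for mesenchymal and matrix genes, CDC42 and PAK signalling, respiratory chain, p53 targets, TGF-beta and BMP, fibroblast markers and EWS-FLI1 activated genes.

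Only APOE was called in opposite directions against scramble: -0.38 ± 0.10 under the mimic (adjusted p = 0.0201) and 0.69 ± 0.10 under the anti-miR, a difference of -1.07 ± 0.10, adjusted p = 0.000125. A further 8 genes were called in the same direction by both reagents: PTPMT1, ZNF804A, ADI1 and CHST1 higher, GALNT16, CA5B, BMP6 and BBS2 lower. Independent lists of these sizes would share 1.21 in the same and 1.22 in opposite directions, a figure that does not allow for the shared scramble arrays. Simulations in which all groups, scramble included, were drawn unchanged shared 0 and 0. With no changed genes in either simulated group such overlaps could hardly arise, so these simulations are no measure for the 8 genes. Whether the shared scramble arrays account for the 8 was not tested. The anti-miR call of APOE was lost in all but 3 of the 12 leave-outs, those of mimic 2 and 3 and anti-miR 2 (adjusted p up to 0.139). Both counts were 0 under median scaling. The count in the same direction was 0 without scramble 1, 2 or 3, mimic 1 or 4 or anti-miR 1, 3 or 4, 1 without scramble 4, 5 without mimic 2 or 3 and 18 without anti-miR 2, and it ran from 0 to 33 (array weights) over 16 other settings, with 22 for trended and robust variance and 2 with the replicate block.

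Across genes, which are not independent replicates, the fold changes of the 2 comparisons correlated at r = 0.36 (Spearman's rank correlation 0.37). In simulations all groups, scramble included, were drawn unchanged and each gene on its own, and r was 0.50 (0.475 to 0.522). Genes drawn in this way do not move together, so that range is no measure of the spread of r here. With the measured scramble arrays split between the comparisons r was 0.0864 to 0.264. The covariance was 0.0180 against a simulated 0.00760, a difference of 0.0104. Leaving out 1 array moved r between 0.28 and 0.46, leaving out both arrays of lowest intensity gave 0.18, and with raw intensity as a covariate it was 0.03.

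**Figure D3:**
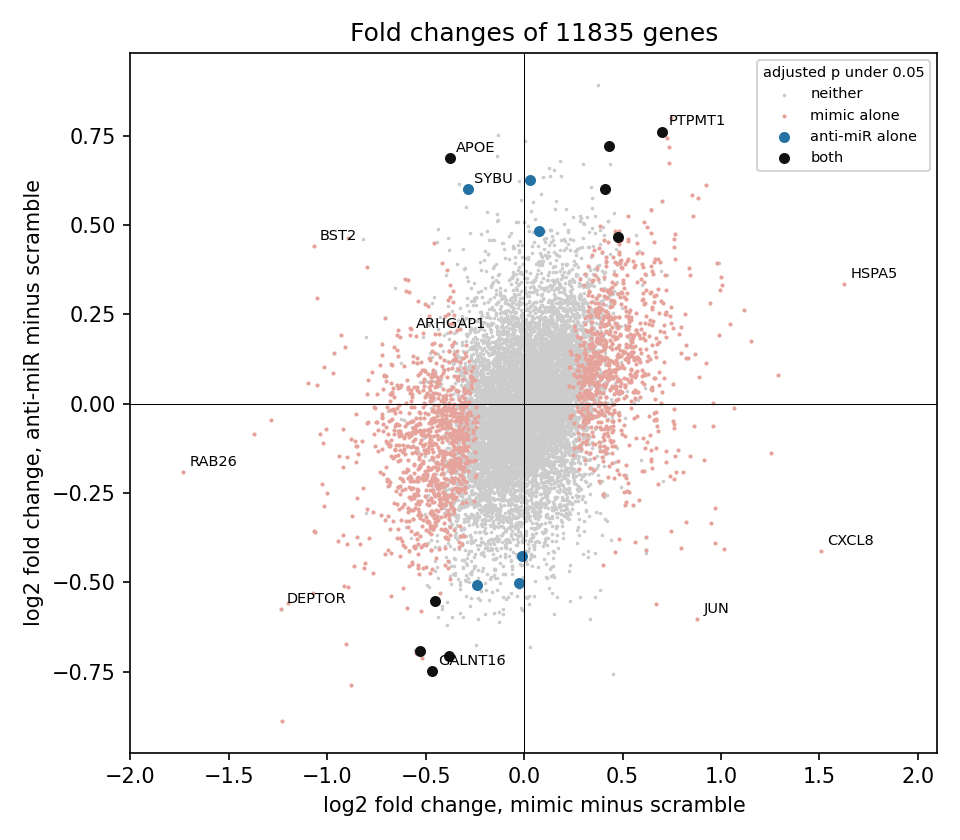
Log2 fold change of 11835 genes under the mimic (horizontal) and the anti-miR (vertical), each against the same scramble arrays; colours mark genes called in 1 or both comparisons. The called genes spread along the mimic axis, 1919 against 15, and APOE is the gene called in opposite directions.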

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

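The tests of HSPA5 as the sole source of the unfolded protein response and of a response to introduced double-stranded RNA were chosen only after the result they measure was seen.

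The rise of protein folding genes under the mimic is a pattern to follow up, since reagent handling and nutrient supply can raise the same genes. The rise did not rest on HSPA5 alone: without it the unfolded protein list still had a mean of 0.37 (SE 0.11, exact permutation p = 0.0286, the smallest possible). That mean follows from the members' values, of which 26 of 27 read above 0, and is no separate test. Leaving out several abundant genes together was not tried. Glucose shortage stays open: TXNIP, which falls when glucose is low, changed by -1.23 ± 0.36, adjusted p = 0.0328. Under the anti-miR it changed by -0.89 ± 0.36, adjusted p = 0.245, and there the unfolded protein list had a mean of 0.01. Over the 12 arrays the deviations of HSPA5 and TXNIP from their group means correlated at r = -0.84 (permutation p = 0.00757; Spearman's rank correlation -0.76, permutation p = 0.0261; r = -0.58 without the 2 arrays farthest from the median). ARRDC4, the other glucose-responsive gene named for the test, did not pass the detection filter, so culture conditions and the mimic cannot be told apart for HSPA5. With TXNIP as a covariate the list without HSPA5 kept a mean of 0.36 (SE 0.13). That fit leaves out HSPA5, and TXNIP is a single gene that itself differed between the groups. It therefore cannot exclude a state tracked by TXNIP as the whole cause of the list's rise. A response to raised miR-130b may remain as a hypothesis.

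Interferon-stimulated genes were lower under the mimic (list mean -0.31, SE 0.088, exact permutation p = 0.0286). Under the anti-miR camera called the list higher, but not with an estimated correlation (adjusted p = 0.702), and fry did not call it (adjusted p = 0.355). A permutation of its array means also missed the threshold (0.16, SE 0.11, exact permutation p = 0.2). Noise among dim genes as the whole source is argued against for the mimic by the 15 brightest of its 30 members (-0.38, SE 0.098, exact permutation p = 0.0286). The 15 dimmest read -0.24 (SE 0.098, exact permutation p = 0.0857). Both are parts of the list that fell, so neither is a separate test of the fall. With raw intensity as a covariate the mean under the mimic was -0.31 (SE 0.12). Median raw intensity was nearly the same on mimic arrays (84.5 to 87.6) and scramble arrays (85.5 to 88.8). That fit could therefore hardly move the value, and no conclusion on array intensity is drawn from it. Whether mimic and scrambled RNA differ in the response they raise as double-stranded RNA stays open, because the fall itself (-0.31) cannot test it. For the anti-miR the covariate left 0.16 (SE 0.19), so there lower array intensity and an effect of the inhibitor cannot be told apart. An effect of raised miR-130b stays among the open explanations of the fall.

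The mimic changed 1919 genes and the anti-miR 15. Noisier anti-miR arrays are argued against: the median SD within that group was 1.01 times that of the mimic group. Chance in which of the 8 treated arrays carry which reagent is not excluded for the larger distance of the mimic arrays from the scramble (root mean square effect 0.23 against 0.14, exact two-sided permutation p = 0.0571 over 70 assignments). For the calls under the mimic and between the reagents, chance in how the arrays were grouped is argued against but not excluded. The real split alone, 1 of 35, reached 1919 genes under the mimic (highest other split 1). Between mimic and anti-miR it alone, 1 of 35, reached 1777 (highest other 1). A share of 1 in 35 is the smallest these splits can give. Under the anti-miR 1 of 35 reached 15 (highest other 2) in the fit of all 12 arrays. That count was 0 with only the groups compared in the fit, under median scaling and in 8 of the 12 leave-outs. Those were of scramble 1, 2 and 3, mimic 1 and 4 and anti-miR 1, 3 and 4, so chance is not argued against there. How far either reagent moved miR-130b itself was not measured here, so a weaker inhibitor may remain among the open explanations.

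An array was taken to stand apart when its gap to the nearest of its group, divided by the group's range, exceeded Dixon's critical value; chance does this in about 1 in 20 groups, and 19 of 375 groups did (5.07%). In the scramble group replicate 1 was high for ATF3 (0.954), JUN (0.846) and GRIK2 (0.833). Scramble replicate 2 was high for LAMP2 (0.847). Scramble replicate 4 was low for COL1A1 (0.863), GALNT16 (0.944), SBF2 (0.915) and WIPF1 (0.833). In the mimic group replicate 2 was high for ARHGAP19 (0.831) and for median raw intensity (0.839), and low for the mean of the unfolded protein list (0.893), at 10.19 against 10.30 for the others. Mimic replicate 3 was high for ADAM32 (0.917) and CTSA (0.984). In the anti-miR group replicate 1 was low for CCN2 (0.909), and replicate 2 was high for CA5B (0.838) and low for SQSTM1 (0.843). Anti-miR replicate 3 was low for STARD13 (0.869) and WASL (0.973), and replicate 4 was high for PFKFB3 (0.918).

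Among 5010 detected probes with no gene name used here, which enter none of the report's comparisons, 312 differed between mimic and scramble, 13 between anti-miR and scramble and 416 between mimic and anti-miR, by the same test.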

How the results depend on the processing

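Leaving out both dimmest arrays (anti-miR 3 and 4) and raw intensity as a covariate were chosen after seeing the data. The mimic count lay between 1444 (median scaling) and 2437 (trended and robust variance) over settings that keep the threshold and all arrays, between 1089 and 2072 with 1 array left out, and was 414 for at least 1.5-fold and 575 at an adjusted p under 0.01, which are stricter by construction. With the authors' normalized values it was 1817, of which 1803 were also among the 1919. The count between mimic and anti-miR was 877 to 1848 with 1 array left out, 381 for at least 1.5-fold, 527 at an adjusted p under 0.01, 1021 without both dimmest arrays and 828 with the covariate.

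The anti-miR count of 15 was not stable, and the cause was not tested: 36 with no background correction, 30 with an offset of 50, 0 with median scaling, 6 with no filter on dim probes, 23 with every probe on its own, 0 with only the groups compared, 99 with array weights, 57 with trended and robust variance, 9 for at least 1.5-fold, 0 at an adjusted p under 0.01, 0 without both dimmest arrays, 0 with the covariate, and 0 to 31 with 1 array left out (20 without mimic 3). In the main fit, which called the 15, limma gave 1958 genes at an unadjusted p under 0.05. Unadjusted counts were not taken for the settings with 0 calls. The 1 gene changed in opposite directions became 5 (no background correction), 5 (offset 50), 0 (median scaling), 2 (detected on all 12 arrays), 2 (every probe), 2 (mean of the probes), 0 (only the groups compared), 5 (array weights), 6 (trended and robust), 0 (1.5-fold), 0 (adjusted p under 0.01), 0 (without both dimmest arrays), 0 (covariate) and 0 to 2 with 1 array left out. The correlation of the fold changes was 0.28 to 0.46 with 1 array left out, 0.18 without both dimmest arrays and 0.0304 with the covariate.

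Replicate numbers did not pair the arrays across all 3 groups: of 12 same-number pairs 2 had a correlation of deviations over 0.1 (-0.22 to 0.23). In both other groups at once, 0 arrays correlated best with their own number. Between mimic and anti-miR the 4 same-number pairs read 0.08, 0.13, 0.23 and 0.04. Each anti-miR array correlated best, among the mimic arrays, with that of its own number, so a weak pairing of these 2 groups stays open. With the replicate block the counts were 1797, 2 and 1590, with 0 in opposite directions.

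Of 84 list tests 21 were called, 17 to 24 with 1 array left out, 21 by fry and 0 by camera with an estimated correlation, which allows for members that move together. Over all alternatives 455 of 525 list values kept their direction and side of the threshold, 69 were no longer called and 1 reversed, the G1/S list under the anti-miR (-0.12 with the covariate). Of 2692 values of named genes 2326 were kept, 362 were no longer called, 2 became called (JUN under the anti-miR, adjusted p = 0.0348 with no background correction and 0.0414 with an offset of 50) and 2 reversed with the mean of the probes: TNC at 0.10 and LAMP2 at 0.0225 under the mimic, whose probes disagree. Seed site tests and the slide block were not run. Signal over background limits genes such as FOS, whose probes were not detected.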

Other observations

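The 4 lists tested first here were written after the largest changes had been seen, and the fifth after those results, so their tests were chosen only after those results were seen. They were not recomputed under the alternatives. Array means gave an exact permutation p of 0.0286, the smallest possible, for the first 4 under the mimic, 0.0536 after adjustment over 15 tests.

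Some genes of the NRF2 oxidative response rose with NQO1 (1.04 ± 0.14) and the pseudogene NMRAL2P (1.11 ± 0.25) under the mimic. Of 18 measured members, none in the lists fixed earlier, 7 rose, 0 fell and 11 did not pass; GCLC, TKT, ME1, BLVRB and EPHX1 read below 0. Those that rose include SRXN1 (0.91), TXNRD1 (0.76) and GCLM (0.76), which encode enzymes of peroxiredoxin, thioredoxin and glutathione metabolism. The list mean was 0.27 (adjusted p = 0.00112; adjusted p = 0.197 with an estimated correlation), and -0.01 under the anti-miR (adjusted p = 0.518). Of genes that FOXO transcription factors raise some fell along with CCNG2, KLHL24, TXNIP, DEPTOR and YPEL3 (-1.02). Of 21 measured, 6 of which other lists hold, 4 fell, 0 rose and 17 did not pass. KLF9 (-0.67), ERBB3 (-0.63), BCL6 (-0.49) and CITED2 (-0.44) fell, and SESN3, GABARAPL1 and BNIP3 read above 0. The list mean was -0.23 (adjusted p = 0.00112; adjusted p = 0.324 with an estimated correlation) and -0.16 under the anti-miR (adjusted p = 0.00367; adjusted p = 0.362 with an estimated correlation), there with 0 called members, a 95% interval of -0.34 to 0.01 and an exact permutation p of 0.0571 (0.0857 adjusted). The difference between the reagents was not called (-0.07, adjusted p = 0.216).

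As a list, genes of MHC class I antigen presentation were lower beside the interferon genes. Of 13 measured 2 fell and 11 did not pass; the 2 are the proteasome activator gene PSME1 (-0.66 ± 0.09, adjusted p = 0.00127) and HLA-E (-0.41 ± 0.08, adjusted p = 0.006), whose probe may also bind related HLA transcripts. The list mean was -0.18 (adjusted p = 0.0254; adjusted p = 0.324 with an estimated correlation). Targets of the let-7 family were higher as a list: of 24 measured, 2 of which other lists hold, 9 rose and 1 fell. ARID3A (0.72), SLC20A1 (0.66) and E2F6 (0.59) rose, next to LIN28B (0.67), ARID3B (1.02) and CDC25A (0.99) that had prompted the list. PXDN fell (-0.47), and HMGA2 (-0.14), HMGA1, IGF2BP2, SMARCAD1, GNPTAB and NAP1L1 read below 0 without passing. The mean was 0.20 under the mimic (adjusted p = 0.00112; adjusted p = 0.0608 with an estimated correlation) and -0.02 under the anti-miR (adjusted p = 0.988), and the difference between the reagents was 0.22 (adjusted p = 0.00111; adjusted p = 0.0608 with an estimated correlation).

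These 4 lists met what had been written for them before they were tested (means of 0.27, -0.23, -0.18 and 0.20). The FOXO list was lower on average with either reagent against the same scramble arrays, and no hypothesis is drawn from it. The other 3 may be taken as hypotheses. Raised miR-130b in these cells may go with higher NRF2 response genes, with lower antigen presentation genes, and with less let-7 activity. The list means above are their only tests, and whether LIN28B has a part in the last was not tested. The last has a rival, that a large dose of mimic displaces other microRNAs from shared machinery, in which case targets of miR-15/16 and miR-29 should rise as well. Of 27 measured targets of these families, 9 of which other lists hold, 4 rose and 0 fell (CHEK1 0.57, DNMT3B 0.72, TDG 0.48 and WEE1 0.44), and their mean was 0.10 (95% interval -0.03 to 0.24, adjusted p = 0.110, exact permutation p = 0.171). That interval holds both no displacement and a rise as large as that of the let-7 targets, so the 2 explanations cannot be told apart. In the contrast of mimic with anti-miR their mean was 0.20 (adjusted p = 0.00274; adjusted p = 0.197 with an estimated correlation). Under the anti-miR against scramble their mean was -0.10 (95% interval -0.19 to -0.0055, camera adjusted p = 0.0797, exact permutation p = 0.0571). The 0.20 thus also holds a lower mean under the anti-miR, and it does not decide on displacement by the mimic.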
